A study of Mus musculus with 12 samples.

How the data were processed

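The samples were mouse neural progenitor cells, cells that divide in culture and can give rise to neurons and glia, grown with 10 ng/ml each of the growth factors EGF and FGF-2. Cells with loxP-flanked (floxed) Lmnb1 alleles and cells with wild-type Lmnb1 both received a lentivirus that expresses Cre recombinase from a Sox2 promoter. Both also carried a Cre-dependent EYFP reporter, and EYFP-positive cells were isolated by fluorescence-activated sorting 5 or 9 days later, per the labels' protocols. Polyadenylated RNA was sequenced from 12 libraries in 4 groups of 3, named here WT and cKO (the floxed genotype) at day 5 and day 9. The labels do not say whether replicates came from separate cultures or animals, so p-values measure only the spread between these samples, which may be technical.

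The authors deposited estimated (expected) counts per gene and, in separate tables, TPM values (transcript abundances scaled for transcript length and library total) per gene. RSEM, Bowtie2 and the build mm10 are named in the submitters' processing notes, and per the file headers the columns hold RSEM gene results of single-end reads. Tool versions, the gene annotation, read trimming and strand use are not given in the sources used here. Without strand information, reads from a gene and from an antisense or overlapping gene cannot be told apart, and near-identical copies such as the beta protocadherins and pseudogenes share reads, so their values are uncertain. Each day had its own tables, with 43309 features at day 5 and 42802 at day 9. Day 5 features carried Ensembl identifiers, of which 42425 (97.96%) were paired with a symbol, and day 9 features carried symbols, of which 41839 (97.75%) were in the reference gene names. Neither table listed mitochondrially encoded genes. The deposited expected counts were rounded to whole numbers. The deposited TPM values, which are not counts, were used only in alternative tests. At day 9 the 12 structural RNA features named below held 16.98%, 36.34% and 19.29% of the TPM total in the WT libraries and 69.39%, 0.5494% and 69.42% in the cKO libraries.

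Genes were tested in R 4.3.3 with edgeR 4.0.16: filterByExpr by group, TMM scaling, robust quasi-likelihood fit (glmQLFit) and test (glmQLFTest), with Benjamini-Hochberg adjustment and a threshold of 0.05. Each day was fitted alone on its 6 libraries, cKO against WT, with no covariate. The day difference was tested on all 12 libraries with 1 mean per group, as the day 9 change minus the day 5 change, over the 41592 symbols found once in both tables. Log2 fold changes are cKO minus WT, with standard errors from the F statistic (the size of the log2 fold change divided by the square root of F). Means with SD over 3 libraries are in CPM, counts scaled to a common library size after TMM. Levels were not compared between days, since day and table cannot be told apart.

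Gene lists were tested with camera of limma 3.58.1 on log2 CPM (prior count 2), with the inter-gene correlation preset to 0.01, adjusted over the lists of that day with at least 3 tested members. The 30 lists were: nuclear lamina and envelope; neural stem and progenitor markers; neuronal differentiation markers; synaptic genes; astrocyte, oligodendrocyte lineage, ependymal, microglia and macrophage, endothelial, and mural and fibroblast markers. Others were S phase, G2 and M phase, p53 targets, senescence and secreted factors, interferon response, MHC class I and antigen processing, integrated stress and unfolded protein response, cholesterol synthesis, and glycolysis and hypoxia response. The rest were Notch targets, Wnt targets, BMP and TGF-beta targets, growth factor immediate early genes, extracellular matrix and adhesion, Hox genes, germline genes, beta protocadherins, heterochromatin and DNA methylation factors, cytosolic ribosomal proteins and mitochondrially encoded genes. Hox genes had 0 tested members at both days and the mitochondrially encoded genes none listed, so neither list was tested. The germline list had 2 tested members at each day and the microglia and macrophage list 1 at day 9, so camera was not run on them.

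Named genes followed a rule. Per day it took Lmnb1, then the 8 largest rises and 8 largest falls among genes past the threshold with a mean of at least 5 CPM and no overlap between the groups, leaving out Gm-numbered, Rik, pseudogene and unnamed features. It then took up to 4 members past the threshold with the smallest adjusted p from each list that was called or had such a member, or at most 2 with the smallest p as values if none passed. With under 5 genes past the threshold at a day, the 10 with the smallest p were given as values. For the day difference it took up to 10 genes with the smallest adjusted p, with the same exclusions. A few genes that the rule took are not reported here. The groups, the tests, the gene lists, this rule and the first set of alternatives were fixed before the data were examined.

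The alternatives chosen then were DESeq2 1.42.0, limma-voom, DESeq2 size factors in edgeR, no filter on low counts, a filter of at least 1 CPM in 3 libraries, 1 fit of all 12 libraries, limma on log2(TPM + 1) and log2(TPM + 0.1), the replicate number as a block, an estimated inter-gene correlation, and leaving out each library. Alternatives chosen after seeing the data were the removal of 12 structural RNA features, their share as a covariate, TPM rescaled to the total outside them at day 9, thinning of the day 9 counts to equal depth, 1 surrogate variable from sva 3.50.0, and the removal of pairs of libraries that stood apart. The 12 features are Gm42418, Lars2, Gm15662, Gm26917, Mir6240, Mir6236, n-R5-8s1, Rn7s1, Rn7s2, Rn7sk, Rmrp and Rpph1; Lars2 is protein-coding and was included because its share moved with that of Gm42418. Gene positions, exonic lengths and transcript GC content came from GENCODE M21 on the mm10 build. Plots were drawn with matplotlib 3.10.9.

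The tests were tested on simulated data drawn from the real means, the trend of the dispersions over expression level and the library sizes. In each comparison 200 genes were changed. With so few changed genes the adjusted threshold was stricter than in the real data at day 9, where 6378 genes passed. The recovered shares given here are therefore no measure of the real day 9 test. For day 5 (14631 genes run), 1.49% of the genes changed 1.5-fold, 0% of those changed 2-fold and 50% of those changed 4-fold were recovered, with 6 false calls. For day 9 (14433 genes run), the shares were 1.49%, 26.9% and 90.9%, with 1 false call. For the day difference (15173 genes run), they were 0%, 1.49% and 36.4%, with 1 false call. In a camera run on simulated counts, a list of 30 genes moved 1.5-fold was called with an adjusted p of 0.000122 for day 5 and 3.11e-12 for day 9, and 0 of 20 unmoved lists were called. The simulated genes were drawn independently of each other. The run therefore does not show how often unmoved lists are called where genes move together. In the real libraries, splits that mix the genotypes had up to 9 lists called at day 5 and up to 15 at day 9.

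Within each group the closest pair of libraries differed by a chi-square per degree of freedom of at least 4.949, above the value of 1 that sampling noise gives, so no library was counted as a duplicate. This does not show that 2 libraries came from separate cultures. The lowest value belonged to cKO replicates 1 and 3 of day 9, while replicate 2 stood at 1594 and 1566 from them. That group thus held 2 much alike libraries and 1 far from both. Total counts per library ran from 26720476 to 32127629 at day 5 and from 13315273 to 24662809 at day 9. The counts outside the structural RNA features fell to 3671634 and 3948154 in 2 of the day 9 cKO libraries, which limits the precision for genes of low level there.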

Results

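RNA was measured in cultured mouse neural progenitor cells with and without a floxed lamin B1 gene after delivery of Cre, to ask which genes change when this nuclear lamina protein is lost. The 12 libraries form 4 groups of 3: WT and cKO at day 5, and WT and cKO at day 9 after the virus. At day 5 the library totals in replicate order were 30124694, 32127629 and 29460342 counts in WT and 28540036, 26720476 and 28068490 counts in cKO. At day 9 they were 24412935, 24662809 and 24501672 counts in WT and 13315273, 22988447 and 13709733 counts in cKO.

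Libraries differed widely in the share of counts on 12 features grouped here as structural RNA, chiefly Gm42418. The group includes Lars2, a protein-coding gene, since its share moved with that of Gm42418 at day 9: Lars2 took 0.545%, 1.213% and 0.5998% of counts in WT and 9.626%, 0.04404% and 10.31% in cKO. What its counts stem from was not tested. At day 9 the share of the group was 15.89%, 34.94% and 17.89% in WT and 72.43%, 0.3615% and 71.2% in cKO, so cKO replicate 2 lay below every WT library and the other cKO libraries above them. At day 5 it was 14.22% in cKO replicate 2 and between 0.0745% and 0.509% in the other 5 libraries.

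Lmnb1, which encodes lamin B1, lies on chromosome 18 from 56707813 to 56753424 on the forward strand (mm10) and has 11 exons in its first annotated transcript. Gene-level counts do not show which exon was removed. At day 5 Lmnb1 was at 288.3, 255.1 and 247.4 CPM in the WT libraries and at 37.8, 40.7 and 45.04 CPM in the cKO libraries, and it fell 6.40-fold (log2 fold change -2.68 ± 0.20 SE, n = 3 per group; edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.0493). At day 9 Lmnb1 was at 155.7, 209.7 and 187.9 CPM in WT and at 34.3, 32.8 and 39.4 CPM in cKO, and it fell 5.20-fold (log2 fold change -2.38 ± 0.14 SE; edgeR adjusted p = 1.85e-05, Benjamini-Hochberg). All 6 cKO libraries lay far below the WT libraries of their day, as their labels say. The day 5 call of Lmnb1 lay close to the threshold: it ended when any 1 of the 6 day 5 libraries was left out (edgeR adjusted p from 0.13 to 0.582, Benjamini-Hochberg), while the log2 fold change stayed between -2.76 and -2.60.

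**Figure D1:**
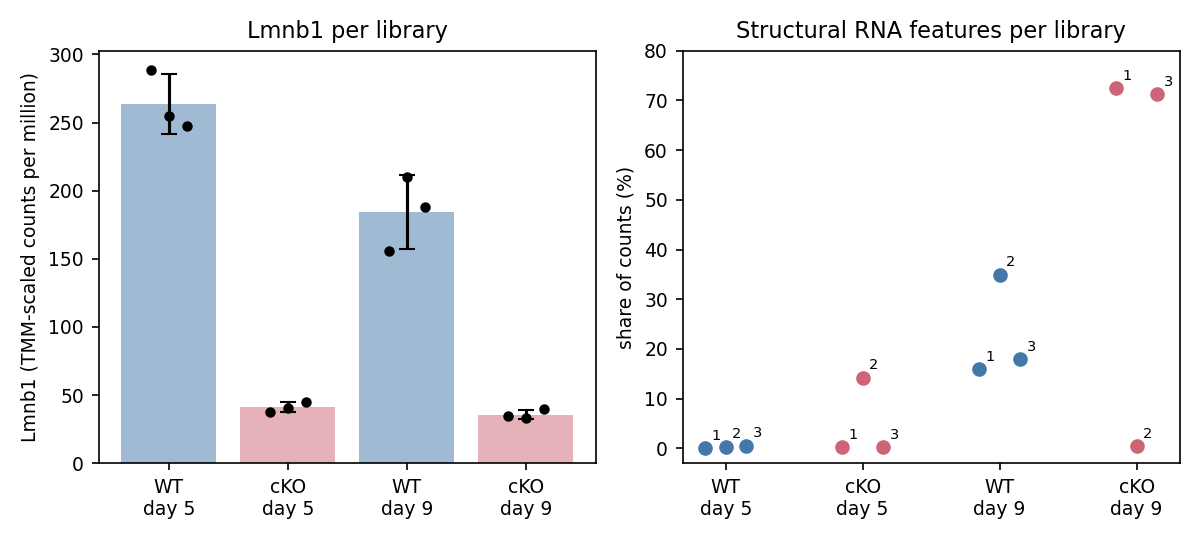
Left, Lmnb1 in TMM-scaled CPM per library (points), with group means (bars) and SD (error bars, n = 3). Right, percent of each library's counts on the 12 structural RNA features, with replicate numbers beside the points; at day 9 the cKO libraries lie at 72.43%, 0.3615% and 71.2%.

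The first comparison asks what differed between cKO and WT cells 5 days after the virus. Lmnb1 was the only gene of 14849 tested to pass: 0 genes rose and 1 fell. By gene lists, the oligodendrocyte lineage markers, the cholesterol synthesis enzymes, the Notch targets and the ribosomal proteins were lower as groups in cKO by camera at the preset correlation, each by a small amount. None of the 27 tested lists was called with an estimated correlation (adjusted p = 0.461, 0.461, 0.686 and 0.846 with an estimated correlation for these 4 lists, in the same order). There 2 lists had an unadjusted p under 0.05. The oligodendrocyte markers had a median log2 fold change of -0.37 over 16 tested members, and cholesterol synthesis -0.26 over 24.

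Within those 4 lists 0 members passed, also when adjusted over the list alone. Gpr17, a receptor of immature oligodendrocytes, was at 90.3 ± 10.7 CPM in WT and 44.5 ± 15.3 in cKO (mean ± SD, n = 3), and Mbp, a myelin protein, at 5.65 ± 1.19 and 3.58 ± 0.82. The sterol enzymes Lss and Nsdhl were at 290 ± 57.1 and 207 ± 13.1 CPM in WT and at 215 ± 6.82 and 157 ± 23 in cKO. Among 13 Notch targets (median -0.21), Hes5 was at 28.5 ± 7.94 CPM in WT and 16.7 ± 7.19 in cKO, and Nrarp at 51.1 ± 10.2 and 37.5 ± 5.43. Of 75 ribosomal protein genes (median -0.09), Rpl17 was at 210.1 ± 37.2 CPM in WT and 177 ± 35.9 in cKO, and Rpl21 at 428 ± 64.7 and 378 ± 65.3. The camera adjusted p was 1.43e-08 for oligodendrocyte markers, 6.62e-07 for cholesterol synthesis, 0.00429 for Notch targets and 0.00418 for ribosomal proteins. The call of cytosolic ribosomal proteins at day 5 ended without WT replicate 2 (median -0.05, camera adjusted p 0.152), without WT replicate 1 and cKO replicate 2 together (0.584) and with 1 surrogate variable (0.363). Its median turned positive without WT replicate 3 (0.06, camera adjusted p 0.606), and without cKO replicate 2 the list was called higher (0.14, camera adjusted p 6.71e-05). The call of Notch targets at day 5 ended without WT replicate 3 (camera adjusted p 0.0678) and without cKO replicate 2 (0.0641), and without WT replicate 1 the number of lists called was 11, 4 of them higher. The other lists tested at day 5 were not called, and among their members Lmnb1 alone passed, in the nuclear lamina and envelope list (20 members, median 0.01; also 1 adjusted over the list alone).

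Next to Lmnb1, the 10 genes with the smallest p at day 5 did not pass (edgeR adjusted p = 0.9999 for each, Benjamini-Hochberg). Mrps36-ps1 was at 0 CPM in the WT libraries and 0.85 ± 0.17 in cKO (n = 3), and Gm12396 at 0 in WT and 2.07 ± 1.71 in cKO. Gm27177 was at 0.136 ± 0.179 CPM in WT and 10.5 ± 3.96 in cKO, 1500015A07Rik at 1.11 ± 0.351 and 9.86 ± 5.69, and 1700034P13Rik at 9.67 ± 1.69 and 27.3 ± 4.10. Gm37416 was at 49.7 ± 2.88 CPM in WT and 103 ± 5.05 in cKO, Gm10524 at 38.9 ± 1.34 and 79.3 ± 2.06, and Asb18 at 3.10 ± 0.347 and 7.34 ± 0.687. C030005K06Rik was at 1.85 ± 1.23 CPM in WT and 0.293 ± 0.039 in cKO, and Sfrp4 at 0.93 ± 0.176 and 2.87 ± 1.13. Across all genes 89 had an unadjusted p under 0.05 in edgeR; DESeq2 called 8 genes, limma-voom 2 and limma on TPM 3. The biological coefficient of variation, the common spread of genes within genotypes, was 0.405 at day 5 and 0.267 at day 9. The largest chi-square per degree of freedom between 2 libraries of 1 genotype was at day 9, however. It was 1594 for cKO replicates 1 and 2, against 667.9 at most at day 5. Leaving out WT replicate 1 and cKO replicate 2 of day 5 together, chosen after seeing the data, gave 19 changed genes, 12 higher and 7 lower.

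The second comparison asks the same at day 9. In cKO, 13 of 17 oligodendrocyte markers rose and 4 fell, and 16 of 20 astrocyte and 15 of 22 neuronal markers rose. Of the genes of G2 and M phase 41 of 52 fell, of S phase 29 of 38, of growth factor response 16 of 24, of glycolysis and hypoxia 14 of 23, and of ribosomal proteins 43 of 75. Camera called these lists at the preset correlation, but none of the 26 tested lists with an estimated correlation (lowest adjusted p = 0.113 with an estimated correlation). Mbp, a main myelin protein, rose from 4.36 ± 0.892 CPM in WT to 111 ± 21.9 CPM in cKO (mean ± SD, n = 3), and the astrocyte filament gene Gfap from 16.1 ± 2.20 to 334 ± 49.8 CPM. Dusp6 and Etv5, genes switched on by FGF and ERK signalling, fell from 80.3 ± 19.8 and 312 ± 17.2 CPM to 3.43 ± 0.825 and 14.7 ± 1.93 CPM. Of 14617 genes tested, 3070 rose and 3308 fell.

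Of 17 tested oligodendrocyte lineage markers, 13 rose and 4 fell (the same adjusted over the list alone), with a median log2 fold change of 2.41. Enpp6, a marker of newly forming oligodendrocytes, rose from 0.165 ± 0.0174 to 44.1 ± 11.7 CPM (log2 fold change 8.03 ± 0.29 SE), and Bcas1 from 24.8 ± 6.16 to 512 ± 89.6 CPM. Myrf, the transcription factor of myelin genes, rose by 3.74 ± 0.13 and the tight junction gene Cldn11 by 4.09 ± 0.18 on the log2 scale. The camera adjusted p of the list was 5.2e-05, and adjusted p = 0.290 with an estimated correlation. Of 20 astrocyte markers 16 rose and 2 fell (the same adjusted over the list alone; median 1.66), with a camera adjusted p of 5.2e-05 and adjusted p = 0.320 with an estimated correlation. Besides Gfap they included the gap junction gene Gja1 (2.89 ± 0.16), Ntsr2 (2.13 ± 0.16) and Clu (2.002 ± 0.15). The edgeR adjusted p of these genes lay between 4.81e-06 and 5.58e-05 (quasi-likelihood test, Benjamini-Hochberg).

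Of 22 neuronal differentiation markers 15 rose and 0 fell (the same adjusted over the list alone; median 1.16; camera adjusted p 5.2e-05; adjusted p = 0.113 with an estimated correlation). The neuronal RNA-binding protein gene Elavl3 rose by 1.75 ± 0.15 on the log2 scale, Cntn2 by 2.88 ± 0.26, Nhlh1 by 4.29 ± 0.49 and the neuronal tubulin gene Tubb3 by 1.13 ± 0.15. Cntn2 and Nhlh1 were low, at 0.75 ± 0.158 and 0.0693 ± 0.029 CPM in WT and 5.56 ± 0.401 and 1.46 ± 0.185 CPM in cKO. Of 27 synaptic genes 8 rose and 2 fell (median 0.34; the same adjusted over the list alone). The glutamate receptor genes Gria1 (1.56 ± 0.14) and Gria2 (2.57 ± 0.44) and the GABA receptor gene Gabra2 (2.12 ± 0.36) rose, while Dlg4, a postsynaptic scaffold, fell (-0.55 ± 0.09). The synaptic list had a camera adjusted p of 0.0162 (adjusted p = 0.363 with an estimated correlation), and the call of synaptic genes at day 9 ended without cKO replicate 1 (camera adjusted p 0.0537), with cKO replicates 1 and 3 left out together (median 0.18, camera adjusted p 0.169) and on TPM (0.0913), where the median was -0.42, or 0.365 above the shift of all genes on that scale.

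Of 52 genes of G2 and M phase 41 fell and 1 rose (the same adjusted over the list alone; median log2 fold change -2.29). Cdca3 (-4.12 ± 0.17), the centromere histone gene Cenpa (-4.02 ± 0.18), the condensin gene Ncapd2 (-2.28 ± 0.11) and Ube2c, which drives mitotic exit (-3.07 ± 0.15), fell. Of 38 S phase genes 29 fell and 1 rose (30 and 1 adjusted over the list alone; median -1.76), among them the replication helicase genes Mcm2 (-2.28 ± 0.13), Mcm5 (-2.83 ± 0.18) and Mcm3 (-3.10 ± 0.20). Uhrf1, needed to maintain DNA methylation, also fell (-3.21 ± 0.17). Camera gave an adjusted p of 1.22e-12 for G2 and M phase and 1.05e-09 for S phase (adjusted p = 0.274 and adjusted p = 0.316 with an estimated correlation). The edgeR adjusted p of the named genes lay between 5.34e-06 and 2.46e-05 (Benjamini-Hochberg).

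Of 24 growth factor immediate early genes 16 fell and 1 rose (17 and 1 adjusted over the list alone; median -0.76; camera adjusted p 4.67e-05; adjusted p = 0.197 with an estimated correlation). Besides Dusp6 (-4.60 ± 0.25) and Etv5 (-4.42 ± 0.14), Etv4 (-4.17 ± 0.16) and the FGF feedback inhibitor gene Spry1 (-3.70 ± 0.16) fell. Of 12 Wnt targets 7 fell (the same adjusted over the list alone; median -1.02): Ccnd1, which encodes the G1 cyclin D1, fell from 379 ± 110.2 to 40.3 ± 2.89 CPM, and Nkd1 (-1.06 ± 0.13), Tnfrsf19 (-1.004 ± 0.12) and Axin2 (-1.16 ± 0.17) fell. Of 14 Notch targets 9 fell and 1 rose (the same adjusted over the list alone; median -0.60), among them Lfng (-2.24 ± 0.09), Nrarp (-2.71 ± 0.14), Hes1 (-2.99 ± 0.22) and the ligand gene Jag1 (-2.14 ± 0.17). The camera adjusted p was 0.00769 for Wnt and 0.00305 for Notch targets (adjusted p = 0.197 and adjusted p = 0.274 with an estimated correlation).

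Of 23 genes of glycolysis and hypoxia response 14 fell and 4 rose (the same adjusted over the list alone; median -0.85; camera adjusted p 0.000339; adjusted p = 0.363 with an estimated correlation). Ldha (-1.87 ± 0.14), Eno1 (-1.95 ± 0.16), Tpi1 (-1.67 ± 0.14) and Gapdh (-1.20 ± 0.12), all enzymes of glycolysis, fell. Of 75 cytosolic ribosomal protein genes 43 fell and 2 rose (54 and 2 adjusted over the list alone; median -0.51; camera adjusted p 6.95e-08; adjusted p = 0.501 with an estimated correlation). Rpl29 (-0.54 ± 0.09), Rps2 (-0.90 ± 0.16), Rpl41 (-0.77 ± 0.15) and Rpl23a (-0.66 ± 0.13) fell. Ribosomal proteins took 4.135%, 3.503% and 3.796% of the counts outside structural RNA in WT and 2.463%, 3.179% and 2.458% in cKO; the high value in cKO belonged to the library with the least structural RNA.

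Of 13 genes of MHC class I and antigen processing 9 fell (the same adjusted over the list alone; median -0.94; camera adjusted p 0.00311; adjusted p = 0.197 with an estimated correlation), among them the class I gene H2-K1 (-1.70 ± 0.12), the peptide transporter genes Tap1 (-1.26 ± 0.15) and Tap2 (-1.09 ± 0.17), and Psmb10 (-0.94 ± 0.16). Of 30 p53 targets 12 fell and 4 rose (13 and 4 adjusted over the list alone; median -0.45; camera adjusted p 0.00798; adjusted p = 0.373 with an estimated correlation). The cell cycle inhibitor gene Cdkn1a fell by 1.497 ± 0.17 on the log2 scale, and Plk2 (-1.62 ± 0.16), Gdf15 (-4.78 ± 0.52) and Psrc1, a spindle gene that is also in the G2 and M list (-2.35 ± 0.15), fell too. Gdf15 was low, at 3.11 ± 0.727 CPM in WT and 0.0939 ± 0.0827 CPM in cKO. Of 6 ependymal markers 5 fell (6 adjusted over the list alone; median -1.55; camera adjusted p 0.00769; adjusted p = 0.197 with an estimated correlation). They were low in both groups: Cfap43 fell from 7.19 ± 0.16 to 3.15 ± 0.876 CPM, and Dynlrb2, Rsph1 and Ccno from 0.711 ± 0.0944, 0.71 ± 0.162 and 0.591 ± 0.122 CPM to 0.0419 ± 0.0726, 0.146 ± 0.157 and 0.119 ± 0.106 CPM. The call of Rsph1 at day 9 ended when any 1 library except cKO replicate 1 was left out (edgeR adjusted p from 0.0529 to 0.11, Benjamini-Hochberg). The call of Ccno at day 9 ended when any 1 except cKO replicate 2 was left out (0.0736 to 0.135).

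Of 20 beta protocadherins, adhesion genes that lie side by side and resemble each other, 14 rose and 0 fell (16 and 0 adjusted over the list alone; median 0.80; camera adjusted p 2.97e-06; adjusted p = 0.113 with an estimated correlation). Pcdhb14 rose by 1.72 ± 0.22 on the log2 scale, Pcdhb9 by 1.57 ± 0.25, Pcdhb5 by 0.89 ± 0.17 and Pcdhb16 by 1.54 ± 0.30. On TPM the list median was -0.06, against -0.79 for all tested genes, so the list stood 0.73 above the shift of all genes on that scale. Pcdhb5 was at -0.03, or 0.755 above it.

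The lists that follow were not called by camera at day 9 or had too few tested members for it. Of 20 genes of the nuclear lamina and envelope 8 fell and 4 rose (the same adjusted over the list alone). The falls included the targeted gene Lmnb1, Banf1 (-1.23 ± 0.13), Nup210 (-0.84 ± 0.11) and Tmpo (-0.91 ± 0.16), which is also in the G2 and M list. Of 25 stem and progenitor markers 10 fell and 6 rose (11 and 7 adjusted over the list alone). The progenitor filament gene Nes fell from 302 ± 51.2 to 77.1 ± 10.6 CPM, and Fabp7 fell by 1.35 ± 0.15 on the log2 scale. Of 24 heterochromatin and DNA methylation factors 6 fell and 4 rose (7 and 4 adjusted over the list alone): Dnmt1 (-1.15 ± 0.13) and Suv39h1 (-0.75 ± 0.10) were among the falls. Of 29 matrix and adhesion genes 12 fell and 5 rose (the same adjusted over the list alone); Itga5 (-2.86 ± 0.19), Lama5 (-2.09 ± 0.17), Itgb5 (-1.02 ± 0.10) and Col5a1 (-1.76 ± 0.21) fell. Of 24 cholesterol genes 8 fell and 2 rose (the same adjusted over the list alone), with falls of Ebp (-1.23 ± 0.14), Pmvk (-0.55 ± 0.12) and Srebf2 (-0.41 ± 0.10).

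Of 24 stress response genes 7 fell and 3 rose, of 15 interferon genes 2 fell, of 11 BMP and TGF-beta targets 1 fell and 4 rose, and of 10 senescence and secreted factors 5 fell and 2 rose; each of these counts was the same adjusted over the list alone. The falls included Pdia4 (-0.68 ± 0.09), Shmt2 (-0.42 ± 0.11), Hyou1 (-0.38 ± 0.10), Bst2 (-2.80 ± 0.42), Ifi35 (-1.34 ± 0.31), Id3 (-0.77 ± 0.15), Igfbp3 (-2.87 ± 0.12) and Cdkn2c (-1.59 ± 0.12). The rises included Slc7a11 (2.36 ± 0.43), Id4 (2.56 ± 0.22), Id2 (0.78 ± 0.14; -0.30 on log2(TPM + 1), or 0.487 above the shift of all genes on that scale), Smad7 (1.24 ± 0.25) and Igfbp5 (1.31 ± 0.11). Among markers of other cell types, 2 of 3 endothelial genes fell (Eng, -3.23 ± 0.73, and Flt1, -1.31 ± 0.38) and Kdr rose (0.76 ± 0.25), all under 3 CPM. For Flt1 at day 9 and Kdr at day 9 the call ended when any 1 library was left out (edgeR adjusted p from 0.0537 to 0.105 and from 0.0676 to 0.143, Benjamini-Hochberg), and for Eng at day 9 without WT replicate 2 (0.0536). For Acta2 at day 9 it ended when any 1 library except cKO replicate 2 was left out (0.1004 to 0.173). It ended for Shmt2 at day 9 without WT replicate 2, cKO replicate 1 or cKO replicate 3 (0.0598 to 0.0627), and for Hyou1 at day 9 without WT replicate 2 (0.0502) or cKO replicate 3 (0.0679). Of 5 mural and fibroblast genes Fbln1 (-1.80 ± 0.14), Foxc1 (-1.67 ± 0.26) and Acta2 (-1.37 ± 0.47) fell and Pdgfrb (1.96 ± 0.40) rose, and the 1 tested microglial gene did not pass. The endothelial and mural counts were the same adjusted over the list alone. Of 2 tested germline genes Brdt rose (1.49 ± 0.17; also 1 adjusted over the list alone).

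**Figure D2:**
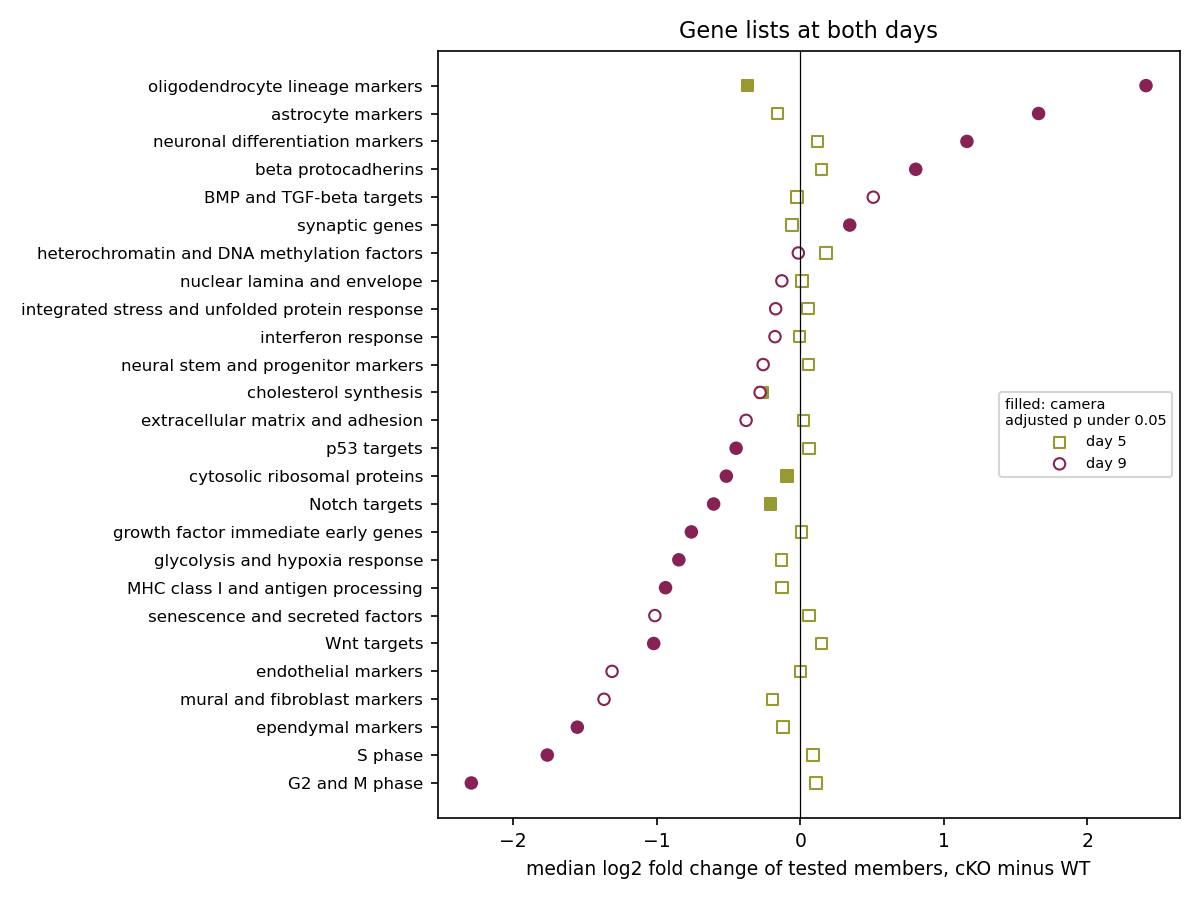
Median log2 fold change (cKO minus WT) of the tested members of each gene list at day 5 (squares) and day 9 (circles); filled symbols mark lists with a camera adjusted p under 0.05 at the preset correlation. At day 9 the medians run from -2.29 (G2 and M phase) to 2.41 (oligodendrocyte lineage).

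Besides the genes above, the largest rises at day 9 were Gng4 (7.28 ± 0.33), Fam129a (4.68 ± 0.37) and Naaa (4.61 ± 0.35), and the largest falls Rab26 (-5.35 ± 0.45), Ngfr (-5.29 ± 0.18), Cd93 (-5.26 ± 0.23), Igfbp4 (-4.87 ± 0.19), the tubulin gene Tuba1c (-4.43 ± 0.59) and Tle6 (-4.38 ± 0.22), each with an edgeR adjusted p of 0.00282 or less (Benjamini-Hochberg). Of the 6378 changed genes, 2937 changed at least 2-fold, 1776 upward and 1161 downward. In 57.8% of tested genes the groups did not overlap, against 2.85% at day 5. For a single gene chance gives 10%, but genes share the structure of the libraries, so the share over all genes can lie far from that value. Camera called 15 of 26 tested lists at day 9, 5 higher and 10 lower, and 0 with an estimated correlation, where 6 lists had an unadjusted p under 0.05. Without cKO replicate 1 the count of changed genes was 4063, and without WT replicate 2 it was 4150. With replicates 1 and 3 of cKO left out together (chosen after seeing the data; the lone cKO library is assumed to vary like the WT libraries) 3169 genes passed, 2763 of them shared with the full set. On the deposited TPM scale the median of all tested genes moved by -0.79 on the log2 scale and limma called 573 genes, 82 higher and 491 lower.

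**Figure D3:**
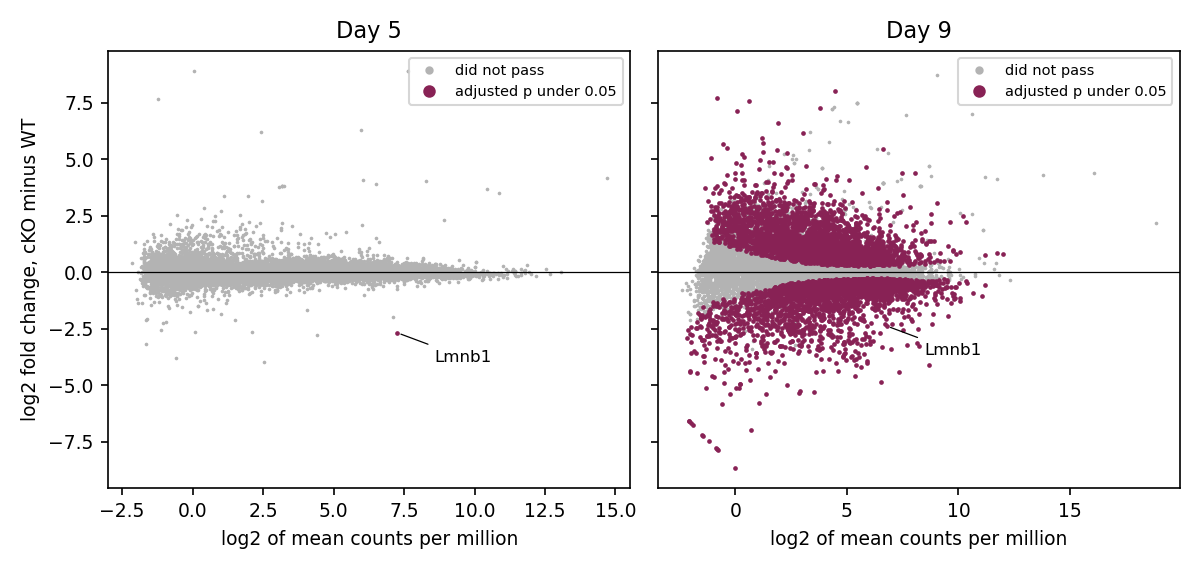
Log2 fold change (cKO minus WT) of each tested gene against the log2 of its mean CPM at day 5 (left) and day 9 (right). Dark points passed an adjusted p of 0.05 in edgeR: 1 gene at day 5 and 6378 at day 9.

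**Figure D4:**
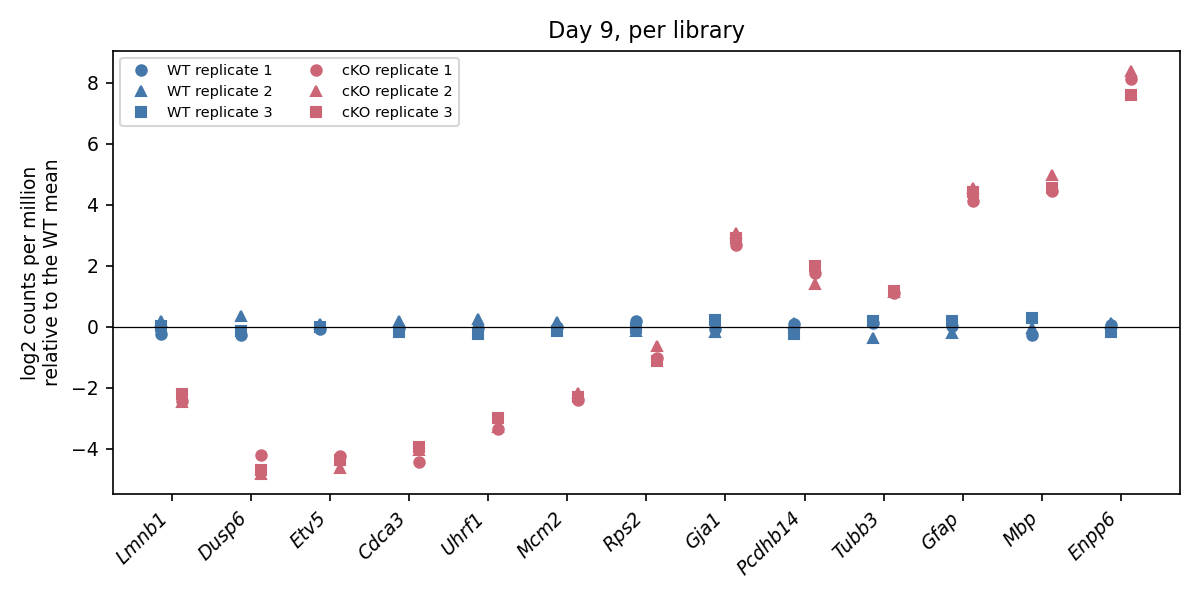
Day 9 expression of 13 named genes in each library, as log2 CPM relative to the WT mean of the gene; symbols mark replicates. The cKO library with little structural RNA (replicate 2, triangles) lies on the same side of WT as the other cKO libraries for each plotted gene. Apart from Lmnb1, the genes were named from their values in these same libraries, so this was largely fixed by their choice.

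The third comparison asks whether the effect of the genotype differed between days. The growth factor genes Etv5, Spry1 and Dusp6 and the mitotic genes Ccnb1 and Knstrn had a more negative change at day 9 than at day 5, and the oligodendrocyte genes Enpp6, Bcas1 and Mbp a more positive one. In the fit of both days, the day 5 log2 fold change was 0.01 for Spry1, 0.18 for Dusp6, 0.21 for Ccnb1, -2.16 for Enpp6, -0.43 for Bcas1 and -0.65 for Mbp. Of 15323 genes tested in all 12 libraries, the change of 1181 differed between days, 394 more positive and 787 more negative at day 9, and 1149 of these had changed at day 9. Etv5 had a log2 fold change of 0.02 at day 5 and -4.41 at day 9 in this fit, a difference of -4.44 ± 0.25 SE. The difference was -3.71 ± 0.22 for Spry1, -4.76 ± 0.29 for Dusp6, -3.84 ± 0.23 for the cyclin gene Ccnb1, -3.94 ± 0.26 for the spindle gene Knstrn and -3.30 ± 0.21 for the kinase gene Lyn. It was 10.21 ± 0.67 for Enpp6, 4.80 ± 0.32 for Bcas1, 5.32 ± 0.36 for Mbp and 4.39 ± 0.30 for the zinc transporter gene Tmem163. Enpp6 was below the low count filter at day 5, with 15, 6 and 7 counts in WT and 1, 3 and 1 in cKO. Its day 5 value and its difference are imprecise. The adjusted p of these 10 genes was between 2.04e-05 and 2.48e-05 (edgeR's quasi-likelihood test, Benjamini-Hochberg). The change of Lmnb1 did not pass: its difference was 0.30 ± 0.20 SE (edgeR adjusted p = 0.476, Benjamini-Hochberg).

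A difference between the tables cancels in this contrast only if it acts alike on WT and cKO. The count was 2410 without day 5 cKO replicate 2, 769 without day 5 cKO replicate 3, 773 without day 9 cKO replicate 1 and 756 without day 9 WT replicate 2; with both WT replicate 1 and cKO replicate 2 of day 5 left out it was 2535, and with a single day 9 cKO library 452.

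Across the 13505 genes tested at both days, the log2 fold changes of day 5 and day 9 had a Pearson r of 0.297 and a Spearman rho of 0.301; genes are not independent replicates. Of the 6008 genes in this set that changed at day 9, 67.3% had the same sign at day 5. Lmnb1 was the 1 gene that passed at both days (Fisher's exact test of the overlap, 2-sided p = 0.445; with 1 gene at day 5 the test could not pass). Without WT replicate 1 and cKO replicate 2 of day 5 the r was -0.0757, so the correlation did not hold without those 2 libraries. They were picked after seeing the data, and r was not computed with other libraries left out.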

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

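The gene list test of the day difference, the carry-over test, and the structural RNA covariate tests of the oligodendrocyte and astrocyte lists were chosen only after the results they bear on were seen. The covariate and thinning tests of the cell division lists were worded before they were run, but after the structural RNA shares had been seen, and the margin of 1 standard error used to read the covariate and thinning tests was set after those results. The minimum level asked of the markers in the carry-over test was added after its result too.

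The change between cKO and WT differed between day 9 and day 5 for 1181 genes by the test of the difference itself. The 10 named genes differed by -4.44 (Etv5), -3.71 (Spry1), -3.84 (Ccnb1), -4.76 (Dusp6), -3.30 (Lyn), -3.94 (Knstrn), 10.2 (Enpp6, which had at most 15 counts per library at day 5), 4.80 (Bcas1), 5.32 (Mbp) and 4.39 (Tmem163) on the log2 scale. Of 100 splits drawn within days 2 gave at least 1181 genes, the real one included; the other gave 9126 genes. That split kept the real groups at day 9 and set WT replicate 1, cKO replicate 2 and cKO replicate 3 of day 5 against the rest, which points to a structure among the day 5 libraries beyond genotype.

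The S phase and G2 and M phase genes fell together at day 9. Structural RNA content of the libraries stays undecided as a cause. With the log2 odds of that share as a covariate the medians were -2.35 for G2 and M phase and -1.72 for S phase. Without it they were -2.29 and -1.76. The log2 odds had similar means in WT and cKO, since cKO replicate 2 lay far below the other cKO libraries. This left the covariate little room to move these medians. It did move the median of 14 Snora genes from 1.41 to -0.206, so it was not without effect on every gene set. After thinning to equal depth the medians were -2.44 and -1.77. Thinning keeps the expected proportions within each library, so it had little room to move these medians. It does not decide on lower depth in 2 cKO libraries as a cause. A smaller response to EGF and FGF-2 in the cKO cultures at day 9 than at day 5 may contribute and stays open: the growth factor list had a median difference of -0.734 between days (camera adjusted p 6.6e-09; adjusted p = 0.0362 with an estimated correlation), but the G2 and M phase (-2.40), S phase (-1.83), Wnt target (-1.13) and oligodendrocyte (3.10) lists reached the same adjusted p with an estimated correlation. The value largely restates the fall at day 9 that prompted it, so it does not decide, and the response itself was not measured.

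Oligodendrocyte and astrocyte markers rose at day 9. Structural RNA content stays undecided as a cause here too. With the covariate the medians were 1.64 for astrocyte markers (1.66 without, standard error over members 0.338) and 2.38 for oligodendrocyte markers (2.41 without, standard error 0.653). The covariate had similar means in WT and cKO, which left it little room to move these medians. With it both lists were called by camera at the preset correlation (adjusted p 0.000255 and 0.00026). Without the covariate neither was called with an estimated one (adjusted p = 0.320 and adjusted p = 0.290 with an estimated correlation). For both lists, carry-over of other brain cells with mature glia stays undecided: the 9 tested endothelial, mural, fibroblast and microglial markers had a median of -1.31, but 7 of them were under 3 CPM in WT, too low to exclude it, although the EYFP sort would remove unlabelled cells. A shift of cKO cells toward glial expression, or the survival of cells already on that path, may account for the rise and cannot be separated by RNA from sorted pools. Neuronal differentiation markers rose at day 9 as well (15 of 22 higher and 0 lower, median 1.16), so the rise was not particular to glial markers.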

How the results depend on the processing

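Tests with the structural RNA features (rescaled TPM included), a surrogate variable, thinning, or pairs of libraries left out were chosen only after the data were seen; the others were planned. Lmnb1 kept its direction in every alternative run. At day 5 its log2 fold change passed except with the replicate block (-2.68), with no low count filter (-2.73) and with any library left out (from -2.76 to -2.60); at day 9 it passed in all, from -2.50 to -2.28 with a library left out.

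The count of 1 changed gene at day 5 was 0 with the replicate block and with no low count filter, 8 with DESeq2, 2 with limma-voom, 2 with all 12 libraries in 1 fit, 3 with limma on log2(TPM + 1) and 3 on log2(TPM + 0.1). It was 9 with 1 surrogate variable, 19 with WT replicate 1 and cKO replicate 2 left out together, and 0 with each library left out. The 4 lists called at day 5 became 7 with those 2 libraries left out, 2 of them higher and 3 shared with the 4; they were 0 with an estimated correlation and 3 to 11 with each library left out. The call of cytosolic ribosomal proteins was the 1 lost with those 2 libraries left out (camera adjusted p 0.584) and with 1 surrogate variable (0.363).

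The 6378 changed genes at day 9 became 2489 with all 12 libraries in 1 fit, 573 with limma on log2(TPM + 1), 687 on log2(TPM + 0.1), 3060 and 2689 on those scales with TPM rescaled to the total outside structural RNA, 3169 with cKO reduced to 1 library, and 4063 to 7507 with each library left out. The other alternatives gave 5514 to 7660 genes. The 15 lists called were 0 with an estimated correlation and 14 to 18 with each library left out. On TPM the median of all genes moved by -0.79 (TPM + 1) and -1.02 (TPM + 0.1). After rescaling it moved by -0.27 and -0.33, so the structural RNA share of the total accounts for part of the shift and the rest is not explained. On both deposited TPM scales the sign turned for Id2 (-0.30 and -0.31) and Pcdhb5 (-0.03124 and -0.175), and on TPM + 0.1 for Kdr (-0.21), but relative to the shift of all genes they stood at 0.487 and 0.712, 0.755 and 0.847, and 0.814. Of 105 genes named at day 9 besides Lmnb1, the calls of 66 (TPM + 1) and 60 (TPM + 0.1) ended, and of 20 and 23 after rescaling. Calls also ended for 19 genes with all 12 libraries in 1 fit, 15 with cKO reduced to 1 library, 5 with DESeq2, 5 with the replicate block, 3 with no low count filter, and 1 of 96 after thinning. The call of synaptic genes at day 9 ended on TPM + 1 and with cKO reduced to 1 library (camera adjusted p 0.0913 and 0.169). Cytosolic ribosomal proteins at day 5 reversed without WT replicate 3 (0.06) and without cKO replicate 2 (0.14). The causes of the other changes were not tested.

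The 1181 genes that differed between days became 322 with the replicate block, 2535 with day 5 WT replicate 1 and cKO replicate 2 left out, 452 with cKO at day 9 reduced to 1 library, and 756 to 2410 with each library left out. The correlation of 0.297 between days became 0.157 with the replicate block and -0.0757 with the 2 day 5 libraries left out.

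Replicate numbers did not pair the libraries: deviations of WT and cKO libraries with the same number correlated by -0.721, -0.498 and 0.534 at day 5 and by -0.00138, -0.2 and -0.0628 at day 9. With the block, 5514 genes passed at day 9 and 4 and 15 lists were called. Depth limits low genes at day 9, where 2 cKO libraries held 3671634 and 3948154 counts outside structural RNA.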

Other observations

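The family, GC content and day 5 correlation tests, the density test given length, GC content and level, the structural RNA test of ribosomal proteins, and the margin of 1 standard error used to read the list medians, were chosen only after the results were seen.

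Other gene families moved together at day 9. Among 144 families of at least 10 tested genes with a shared symbol stem (288 tests, Fisher's exact test, Benjamini-Hochberg over them), 9 passed. Genes of the mitochondrial ribosome fell, 33 of 47 Mrpl genes (adjusted p = 9.72e-09) and 16 of 29 Mrps genes (adjusted p = 0.0141). So did genes with symbols of respiratory complex I subunits, 12 of 13 Ndufa genes (adjusted p = 5.09e-05) and 9 of 10 Ndufb genes (adjusted p = 0.00131). All 10 Psmb genes, proteasome subunits, fell (adjusted p = 6.22e-05), and so did 19 of 33 Rps genes (adjusted p = 0.00242) and 23 of 45 Rpl genes (adjusted p = 0.0045). The background was 24.8% lower and 21.2% higher among the genes that could have passed. After subtracting the trend on GC content the median moved from -0.655 to -0.5 for Ndufa and from -0.682 to -0.551 for Psmb. It moved from -0.527 to -0.531 for Mrpl, from -0.382 to -0.437 for Mrps and from -0.697 to -0.757 for Ndufb. Gene length was not weighed for these 5 families, while longer genes rose more across all genes (Spearman rho 0.219).

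Of 324 zinc finger genes with the stem Zfp, many of which encode repressors of transcription, 128 rose and 19 fell (Fisher's exact test, adjusted p = 8.18e-12; median 0.521), with a median of -0.302 on TPM, where all genes moved by -0.786. The median was 0.293 after subtracting the trend on GC content, so part of this rise follows GC. Of 20 Pcdhb genes 14 rose (adjusted p = 0.00022), with a median of -0.0578 on TPM, or 0.728 above all genes there. Fisher's test treats family members as independent; as lists, neither the beta protocadherins nor the cytosolic ribosomal proteins were called with an estimated correlation (adjusted p = 0.113 and adjusted p = 0.501 with an estimated correlation).

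The fall of cytosolic ribosomal proteins and the rise of beta protocadherins were weighed against gene length and GC content, which correlated across genes with the day 9 change (Spearman rho 0.219 and -0.355, and 0.289 and -0.447 at day 5, so the trends are not particular to day 9; genes are not independent replicates). Structural RNA content stays undecided as a cause of both. The list medians were -0.522 and 0.804 with the covariate (-0.514 and 0.805 without). That covariate had similar means in WT and cKO, which left it little room to move them. At day 9 the ribosomal protein share was highest in the cKO library with the least structural RNA. In WT it was lowest in the library with the most. Gene length as the whole cause was argued against for ribosomal proteins by a median of -0.356 after subtracting its trend, although it may account for part of the fall, and for protocadherins by direction, since longer genes rose more and their median length of 3736 bases lies below the 4304.5 of the tested genes with a known length (0.825 after subtracting). GC content as the whole cause was argued against by medians of -0.414 and 0.581 (standard errors 0.033 and 0.1) after subtracting its trend, although for the protocadherins it may account for part of the rise. Reads shared between protocadherin copies were not tested, and the genotype stays open as an explanation of both.

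A hypothesis that genes in gene-poor regions rose more at day 9 gave a Spearman rho of -0.221 between the change and the number of protein-coding genes within 1 Mb, but -0.000827 given length, GC content and level, so it stays undecided. At day 5 the rho was -0.333 (-0.0868 given the same 3), and -0.219 without WT replicate 1 and cKO replicate 2 (-0.0579). A hypothesis that sequence linked to the floxed allele alters genes near Lmnb1 was tested within 5 Mb at day 5. There 1 of 41 genes (Minar2) against 86 of 14697 others had an unadjusted p under 0.05 (1-sided Fisher's exact p = 0.216). This does not decide it, and so small a count hangs on the edge of the window. 1500015A07Rik, among the 10 genes with the smallest p at day 5, lies just outside it on chromosome 18 (61726390 to 61735917). C030005K06Rik (50042730 to 50053844) and Gm10524 (82692284 to 82694176), also among those 10, lie farther away on that chromosome. At day 9 the counts were 17 of 39 against 7675 of 14144 (1-sided Fisher's exact p = 0.933).

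The Pearson r of 0.297 between the changes of both days fell to -0.0757 without the 2 day 5 libraries that stand apart. Of 200 combinations of splits 54 gave an r as large (highest other 0.727), so chance cannot be excluded for it. With 10 splits of 6 libraries per day, no share under 0.05 can be reached. At day 5, 2 splits gave at least the real 1 gene, and the highest other gave 4655, with WT replicate 1, cKO replicate 2 and cKO replicate 3 against the rest, a structure of the samples; for the 4 lists it was 4 splits, with a highest other of 9. At day 9, 1 split, the real one, gave 6378 genes and the highest other 0; for the 15 lists it was 2 splits, with a highest other of 15.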
